A study of Mus musculus with 6 samples.

How the data were processed

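Total RNA from mouse embryonic fibroblasts was, per the labels' protocols, converted to biotin-labelled cRNA for Illumina bead arrays. The 6 arrays cover 3 genotypes, each mock transfected or transfected with ISD, with 1 array per group. Groups were taken from the sample titles, which the series' design text bears out, and not from the genotype entry, which conflicts with them. Signal columns were matched to samples through the description of each sample.

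Signals were deposited by the authors as probe intensities on a linear scale for 45281 probes, and no normalization is recorded per the file headers. The columns headed as detection p-values, per the file headers, hold a fraction between 0 and 1 that is highest for the brightest probes. They were therefore read as 1 minus the detection p, and a probe was called detected with a score above 0.99. A table of log2 values was also deposited by the authors. It was checked against the intensities and holds the log2 signal after quantile normalization without background correction, minus the median of each probe over the 6 arrays. All of its values lay within 0.006 of that calculation, so its scale, centring and direction are known; the column medians are 0 or -0.01. The scanner software and its settings are not given in the sources used here.

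From the intensities, background was corrected with the normexp model of limma 3.58.1 in R 4.3.3, with the negative control distribution inferred from the detection values and an offset of 16. Arrays were then quantile normalized and log2 transformed. Of the probes, 34885 have 1 gene symbol in the platform annotation, 18 have several and were left unnamed, and 10378 are not listed there and are unnamed here. Entrez identifiers matched to the RefSeq table of assembly GRCm38.p6 changed 0 symbols. The named probes cover 19057 genes, of which 9915 were detected on at least 1 array. Some list members were not analysed here. Each gene was represented by the probe with the highest mean normalized signal.

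A gene was compared where it was detected on at least 1 of the 2 arrays. Where the dimmer array did not detect it, its value was raised to the lowest normalized signal of detected probes on that array, and the fold is given as a lower bound with the words at least. Folds of 2 or more with the brighter array detected were counted. Medians of gene lists, differences of responses and correlations used values as measured, with undetected signals not raised. Differences of responses were counted for genes detected on at least 1 of the 4 arrays involved. No comparison of 1 array with 1 array allows a test, and a fit over all 6 arrays that takes the ISD effect to be equal in each genotype was not run. Fixed before the data were examined were the groups, the comparisons, the alternatives, 34 gene lists and the rule for named genes. That rule took the 10 largest upward and 8 downward differences for each ISD response, 10 each way between mock arrays, 6 each way between ISD arrays, up to 4 members per gene list, and Trex1, Sting1, Ifnb1, Ifna4, Cxcl10, Ccl5, Il6 and Tnf. Clone names and predicted genes were passed over. The median of each list was placed among 10000 random lists of the same size, matched on mean expression in 10 bins. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

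The steps were tested on simulated data with 200 genes changed by known folds. For a simulated ISD comparison in WT cells, with 14093 genes compared, 48 of 50 genes raised 3-fold and 50 of 50 lowered 3-fold were recovered, as were 50 of 50 at 8-fold in each direction. Of 13893 unchanged genes 3 passed 2-fold. The changed genes were drawn only from brighter genes detected on every array, so recovery of dim genes and lower bounds was not tested. The real comparison in WT cells held 9506 genes, so detection in the simulation differs from that in the data. The simulation holds probe noise only and no variation between cultures. The alternatives were no background correction, normexp without controls and an offset of 50, median scaling, the deposited log2 table, a detection p of 0.05, no detection filter, thresholds of 1.5-fold and 3-fold, the mean of detected probes, and measured values in place of bounds.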

Results

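Gene expression was measured in cultures labelled as mouse embryonic fibroblasts, cells grown from e13.5 embryos of mixed C57BL6/129Sv background, with 1-colour Illumina bead arrays. The cells were wild type (WT), deficient in Trex1 (TKO), or deficient in both STING and Trex1 (STKO). Trex1 is a DNA exonuclease that degrades DNA in the cytosol, and STING is the adaptor through which the cytosolic DNA sensor cGAS activates interferon genes. Each genotype was either mock transfected or transfected for 6 h with 4 µg/ml of ISD, a double-stranded DNA. The design asks how the 3 genotypes differ in cytokine expression with and without this DNA. Each of the 6 groups had 1 array, so no difference between arrays has a replicate check or is given a p-value. The number of arrays limits the precision. The median raw signal ranged from 76.8 to 85.3 across arrays, and 8566 to 9277 genes were detected per array. Where a gene has exactly 2 detected probes, the spread between their log2 differences corresponded to a robust SD of 0.19 to 0.24 per probe, which covers probe error only.

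The targeted genes were examined first, because the genotype entry in the labels conflicts with the sample titles. That entry reads Sting +/+ for both STKO samples and for ISD-treated TKO cells, and Sting -/- for the remaining 3. Groups here follow the titles. Sting1 (Tmem173), the gene for STING, had its lowest signals in the arrays titled STKO, at 118 in mock and 114 after ISD. Its signals were 225 and 501 in WT and 196 and 272 in TKO cells. Sting1 was 2.88-fold lower in STKO than in WT mock cells and 5.37-fold lower in STKO than in TKO cells after ISD. The STKO signals lay just above the lowest detected signals of those arrays (110.8 and 111), and without background correction the difference from WT mock cells fell short of 2-fold, at -0.95 on the log2 scale. Trex1 gave 1088 in WT mock cells, 733 in TKO and 258 in STKO; after ISD the signals were 6386, 849 and 379. Trex1 was thus 1.55-fold lower in TKO than in WT mock cells and 6.86-fold lower after ISD. A second detected Trex1 probe gave log2 differences of -1.21 in mock cells, beyond 2-fold, and -3.20 after ISD. Both genes were detected on all 6 arrays, and whether their probes lie within the deleted parts is not given in the sources used here, so a remaining signal does not test the deletion.

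**Figure D1:**
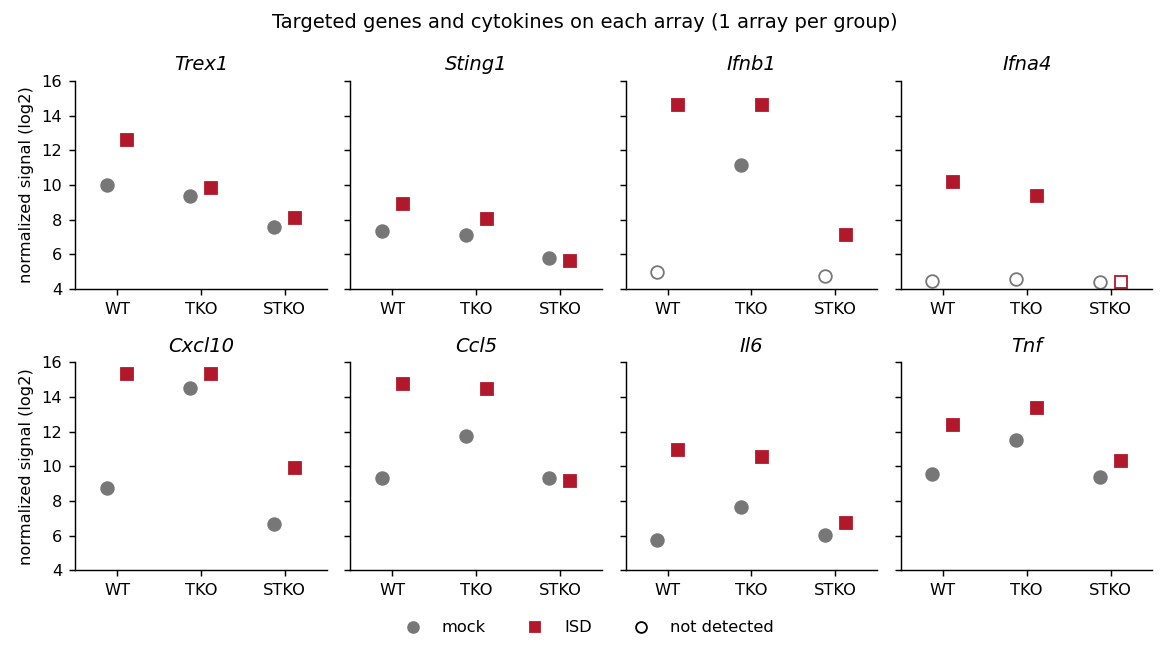
Normalized log2 signal (y axis) of the targeted genes and 6 cytokine genes in WT, TKO and STKO cells (x axis), 1 point per array, circles for mock and squares for ISD, open where the probe was not detected. Ifnb1 reached 14.63 in WT and 14.61 in TKO cells after ISD, against 7.12 in STKO cells.

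ISD transfection of WT cells was accompanied by high expression of interferons, interferon-stimulated genes and chemokines. Ifnb1, which encodes interferon beta, was at least 556-fold higher than in mock cells, where it was not detected. Cxcl9, a chemokine for T cells, was 415-fold higher, Cxcl10 95.4-fold, Ccl5 41.8-fold, Il6 37.4-fold and Tnf 7.03-fold. A second Cxcl10 probe gave a log2 difference of 5.60 against 6.58. In all, 641 of 9506 compared genes were at least 2-fold higher and 428 were at least 2-fold lower. The other genes with the largest upward differences were Cd69 (179-fold), Gbp5 (at least 135-fold), Ccl12 (110-fold), Ifit1bl1 (at least 102-fold), Ifna11 (at least 86.6-fold), Oasl1 (86.4-fold) and Ifna5 (at least 84.1-fold). Ifna4 was at least 25-fold higher.

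Among the fixed gene lists, 49 of 54 measured interferon-stimulated genes were at least 2-fold higher in WT cells after ISD and 0 were lower, with a median log2 difference of 2.63. Oasl1, Cmpk2 (61.5-fold), Mx2 (49.5-fold) and Rsad2 (40.8-fold), all antiviral effectors or their relatives, led this list. Of the type I interferons, 9 of 11 were higher. So were 11 of 18 chemokines, including Ccl8 (21.1-fold), and 12 of 20 inflammatory cytokines, including Il15 (21.1-fold), Tnfsf10 (at least 10.1-fold) and Il33 (9.38-fold). Among targets of NF-kappaB, 18 of 25 were higher, with Cd40 at 31.9-fold, Vcam1 at 13.1-fold and Tnfaip3, a feedback inhibitor, at 7.55-fold. Antigen presentation genes were higher for 12 of 24 members, led by Nlrc5 (13.3-fold), a regulator of MHC class I, and the peptide transporter Tap1 (11-fold). The medians of these 6 lists each lay above those of all 10000 random lists of equal size and similar expression, a description of these arrays only.

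Cell death effectors were higher for 7 of 19 members, including Casp4 (10.8-fold) and Mlkl (5.09-fold). In the cytosolic DNA sensing list, 9 of 26 were higher, with Trex1 at 6.16-fold, Zbp1 at 5.48-fold, Samhd1 at 5.37-fold and Sting1 at 2.99-fold. Immediate early genes were higher for 7 of 23 members, with Dusp2 at 6.50-fold, and lower for 1, Dusp4 (4.62-fold). The largest downward differences were in Gpr183 (17.6-fold), an oxysterol receptor, Mbp (at least 14.2-fold), Slco4a1 (14.0-fold), Fam78a (at least 12.7-fold), E2f2 (at least 11.5-fold), Sesn1 (8.92-fold), the chemokine receptor Cxcr4 (8.33-fold) and Arhgef39 (7.32-fold). A second Mbp probe differed by only -0.43 on the log2 scale. Cholesterol synthesis genes had a median of -0.56 (-0.45 with undetected signals raised), at percentile 0.21 among random lists, with Msmo1 2.29-fold and Stard4 2.11-fold lower. Cell cycle genes had a median of -0.40, with 5 of 33 lower, among them Cdt1 (2.43-fold) and Cdc20 (2.16-fold). Ribosomal protein, oxidative phosphorylation and lysosomal genes had 0 of 23 members each beyond 2-fold in either direction, as had 0 of 24 extracellular matrix genes. The downward count depended on background correction, without which 225 genes were at least 2-fold lower.

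In TKO cells the same DNA was followed by smaller differences from mock. Interferon alpha genes led, with Ifna11 at least 19.4-fold higher, Ifna5 at least 16.4-fold, Ifna2 at least 14.0-fold and Ifna4 at least 13-fold. Ifnb1 was 11-fold higher, from a mock signal that was already 2388. Il27 (15.8-fold), Cxcl9 (14.4-fold), the uridine phosphorylase Upp1 (13.1-fold), Serpina3f (10.1-fold) and the alarmin Il33 (9.14-fold) completed the 10 largest upward differences. Of 9155 compared genes, 305 were at least 2-fold higher and 99 lower. Without background correction 207 were higher and 31 lower. Ccl5 was 6.62-fold, Il6 7.51-fold and Tnf 3.62-fold higher, while Cxcl10 was 1.71-fold higher, from a mock signal of 24690.

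Of 54 interferon-stimulated genes, 19 were at least 2-fold higher in TKO cells after ISD, with a median of 0.79. Ifih1, a sensor of double-stranded RNA, was 4.80-fold higher and Gbp2 3.72-fold. Chemokines were higher for 9 of 18 members, inflammatory cytokines for 9 of 18, and NF-kappaB targets for 8 of 25, including Vcam1 (5.27-fold) and Ptgs2 (3.67-fold). The p53 target list had a median of 0.47, above all random lists, with Fas (4.86-fold) and Sesn2 (3.61-fold) higher and Sesn1 3.99-fold lower. Cell cycle genes had a median of -0.45, below all random lists, although 0 of 30 members passed 2-fold; Aurka was 1.99-fold and Plk1 1.95-fold lower. Gpr183 (5.14-fold), the cannabinoid receptor Cnr2 (4.85-fold), Pdgfb (4.05-fold), Mbp (3.95-fold), Arhgef39 (at least 3.92-fold), Fam78a (3.87-fold) and Cdca7 (3.85-fold) were the other genes with the largest downward differences. Here too a second Mbp probe differed, at 0.13.

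In STKO cells 26 of 9293 genes were at least 2-fold higher after ISD and 1, Ndrg2 (2.34-fold), was lower. Cxcl10 was 9.28-fold higher, the neutrophil chemokine Cxcl2 5.25-fold, the antiviral gene Rsad2 4.69-fold, Cd69 4.22-fold, Ifit3 3.5-fold and Cmpk2 3.02-fold. Icam1, a leukocyte adhesion molecule, was 2.94-fold higher, Ifnb1 at least 2.78-fold, Ccrl2 2.74-fold and Mx2 at least 2.60-fold. Ccl5 was 1.13-fold lower, Il6 1.59-fold higher and Tnf 1.88-fold higher, all short of 2-fold, and Ifna4 was not detected on either STKO array. Interferon-stimulated genes had a median of 0.32 with 5 of 44 higher, and NF-kappaB targets a median of 0.52 with 4 of 23 higher, namely Icam1, Tnfaip3 (2.17-fold), Nfkbie (2.16-fold) and Irf1 (2.06-fold). Both medians lay above all random lists, as did those of p53 targets (0.41), immediate early genes (0.37), chemokines (0.25), the unfolded protein response (0.23, with Chac1 at 2.05-fold) and extracellular matrix genes (0.22). Saa3 (1.99-fold), Tacc1 (1.95-fold), Gng2 (1.93-fold) and Nudt1 (1.87-fold) followed Ndrg2 among the downward differences. Second probes gave log2 differences of -0.02 for Tacc1 and -0.37 for Gng2. Without background correction 14 genes were at least 2-fold higher and 0 lower.

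**Figure D2:**
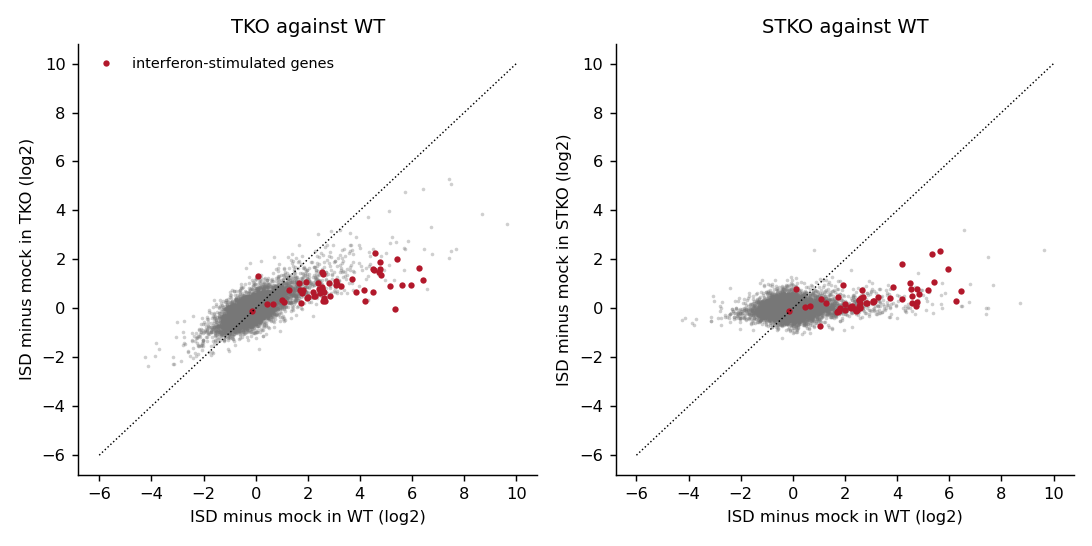
Log2 difference between ISD and mock in TKO (left) and STKO cells (right) on the y axis against that in WT cells on the x axis, 1 point per gene, interferon-stimulated genes in red, dotted line at equality. Across genes the correlation with WT was 0.77 for TKO and 0.21 for STKO.

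Set against each other, the responses differed in interferons and interferon-stimulated genes. By measured values, without bounds, the response of 45 of 55 interferon-stimulated genes was at least 2-fold smaller in TKO than in WT cells. The median difference of responses was -1.98 on the log2 scale. In STKO cells the response of 49 of 55 was at least 2-fold smaller than in WT cells (median -2.50). For type I interferons the corresponding medians were -2.07 and -4.51 over 11 genes. These medians include undetected signals, since only 5 of the 14 genes on the array were compared in the STKO response. Antigen presentation genes had medians of -0.57 and -1.10. The p53 list went the other way, with a response above that of WT cells by a median of 0.66 in TKO and 0.80 in STKO cells, both above all random lists. Its median difference between TKO and WT cells was -0.62 in mock cells, below all random lists, and -0.03 after ISD. Across genes, which are not independent replicates, the Pearson correlation of the WT response with the TKO response was 0.77 (Spearman 0.66), and with the STKO response 0.21 (Spearman 0.10). Of genes compared in both, 263 were at least 2-fold higher in WT and in TKO cells, where independent lists would share 21.2. WT and STKO cells shared 19 against 1.54 for independent lists. None of these pairs of responses shares an array.

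Without ISD, TKO cells already expressed interferon-stimulated genes at high levels relative to WT cells. Of 52 such genes 47 were at least 2-fold higher and 0 lower, with a median of 2.14 as measured and 1.91 with undetected signals raised. Oasl1 was 69.3-fold higher, Ifi205 at least 49.8-fold, Rsad2 39.1-fold, Trim30a at least 38.9-fold, Mx2 32.3-fold and Cmpk2 25.7-fold. Ifnb1 was at least 49.5-fold higher and Cxcl10 55.8-fold, although a second Cxcl10 probe gave a log2 difference of 4.53 against 5.80. Ccl5 was 5.22-fold, Tnf 3.90-fold, Il6 3.77-fold and Cd69 31.4-fold higher, while Ifna4 was detected on neither array. Altogether 375 of 9539 genes were higher and 454 lower.

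Fcer1g, the gamma chain shared by Fc receptors, had the largest upward difference in TKO mock cells, at least 729-fold. It was not detected in WT mock cells, where macrophage markers such as Lyz2 (15.13) were bright. No second probe was detected on both arrays, so a variant under the Fcer1g probe was not tested. Antigen presentation genes were higher for 10 of 24 members, including H2-T10 (4.36-fold) and the MHC class II gene H2-Ab1 (4.15-fold). Extracellular matrix genes were lower for 12 of 24 members (median -1.02), with Fbln2 3.60-fold, Col1a1 3.5-fold, Thbs1 2.92-fold and Col3a1 2.87-fold lower. Regional identity genes were lower for 8 of 23, among them Hoxc6 (2.98-fold) and Foxd1 (2.95-fold). Cell cycle genes were lower for 9 of 33, led by the inhibitors Cdkn2b (11.4-fold) and Cdkn2a (3.80-fold), which restrain division, and by Cdc20 (3.00-fold), which promotes it, while Plk1 was 3.92-fold higher. In the TGF-beta list 4 of 20 members were lower, including Actg2 (4.08-fold) and Tpm2 (3.27-fold). Cholesterol synthesis genes had a median of -0.66, below all random lists. Other large downward differences were in Ifi202b (at least 28.6-fold), Serpina3n (at least 17.9-fold), Rgs4 (at least 12.1-fold), Igfbp2 (10.9-fold), Fcrls (10.8-fold), Elobl (at least 9.50-fold), Hpgd (9.16-fold), Epm2aip1 (at least 8.57-fold) and Bmp4 (8.46-fold). Other Epm2aip1 probes gave log2 differences between -1.30 and 0.20. In the same comparison macrophage markers had a median of -0.31 and fibroblast markers of -0.43.

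Additional loss of STING was accompanied by low interferon-stimulated gene expression. In mock cells 50 of 52 of these genes were at least 2-fold lower in STKO than in TKO cells and 0 were higher, with a median of -2.81. Cxcl10 was 230-fold lower, Oasl1 at least 155-fold, Rsad2 139-fold, Cd69 106-fold, Cmpk2 104-fold, Ifit3 97.1-fold, Mx2 at least 63.9-fold, Ifit2 59.1-fold, Ifi205 at least 45.4-fold and Ifnb1 at least 45.1-fold. The other Cxcl10 probe gave a log2 difference of -6.77 against -7.84. Ccl5 was 5.33-fold, Tnf 4.31-fold and Il6 3.03-fold lower. In all, 242 of 9320 genes were higher and 342 lower.

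Antigen presentation genes were lower for 10 of 24 members in STKO relative to TKO mock cells, with Tap1 at 6.03-fold, and NF-kappaB targets for 9 of 24, with Irf1 at 6.72-fold and Cd40 at 6.53-fold. Cell cycle genes were higher for 8 of 32 members, including Cdkn2b (6.34-fold), Cdc20 (3.34-fold), the centromeric histone Cenpa (3.31-fold) and Birc5 (2.80-fold). Extracellular matrix genes had a median of 0.45, above all random lists, with Fbln1 at 2.21-fold, and fibroblast markers a median of 0.30, at percentile 97.0. Serpina3n (at least 27.9-fold), Fxyd2 (at least 8.22-fold), Hp (7.18-fold), Neurl1a (6.37-fold), Slco4a1 (5.93-fold), Ambp (at least 5.64-fold), Fcrls (5.61-fold), Ly6c1 (5.56-fold) and Hpgd (5.51-fold) had the other largest upward differences. This comparison shares no array with the WT response. The genes at least 2-fold higher in TKO than in STKO mock cells and those at least 2-fold higher after ISD in WT cells had 225 in common, against 21.4 for independent lists, and the correlation across genes was 0.54.

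**Figure D3:**
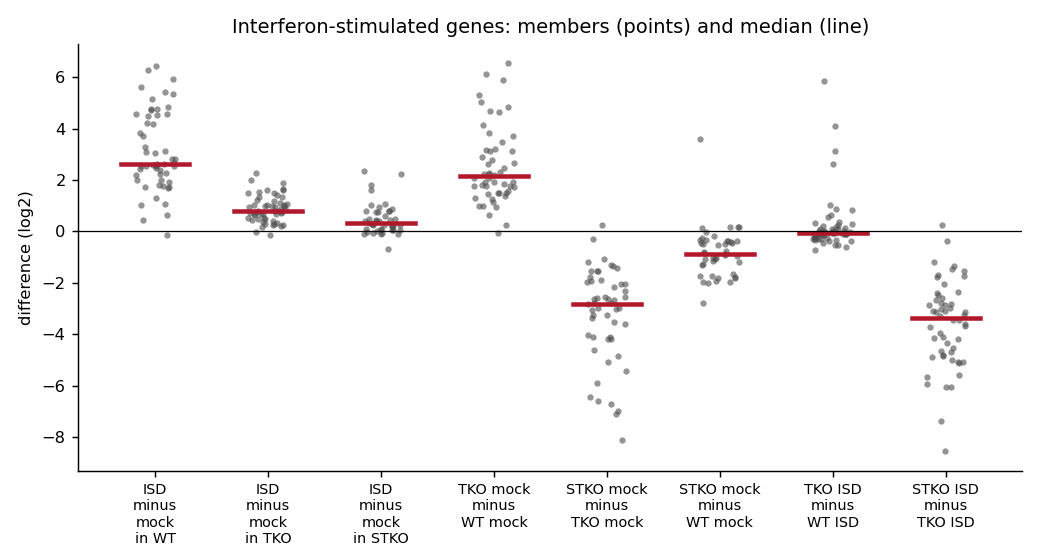
Log2 difference (y axis) of each measured interferon-stimulated gene (points) in the 8 comparisons (x axis), with the median as a red line. The median was 2.14 in TKO against WT mock cells and -2.81 in STKO against TKO mock cells.

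STKO mock cells also differed from WT mock cells, by fewer genes, with 92 of 9487 higher and 165 lower. Of 44 interferon-stimulated genes 18 were at least 2-fold lower and 1, Trim30a (at least 7.77-fold), was higher. The median was -0.88, against -0.59 without background correction, and it was nearer to no difference still without a detection filter. Ifit3 was 6.88-fold, Cxcl10 4.12-fold, Cmpk2 4.05-fold and the interferon regulatory factor Irf7 3.84-fold lower. Ccl5, Il6 and Tnf differed by 1.02-fold, 1.24-fold and 1.11-fold. Fcer1g was at least 681-fold higher, Gdf3, a TGF-beta family ligand, 27.0-fold, the protease Ctsc 14.3-fold, Plk1 9.89-fold, Cd48 at least 8.51-fold, Taf6 6.90-fold, the collagen-degrading Mmp3 5.37-fold, Hp 4.64-fold and Apobec1 4.60-fold. A second Taf6 probe gave a log2 difference of -0.20. Ifi202b was at least 28.9-fold lower, Wdr82 9.34-fold, Rgs4 8.56-fold, Crct1 8.19-fold, Trex1 5.41-fold, Ncam1 5.39-fold, Igfbp2 4.97-fold, Ptprv at least 4.77-fold and Ptn 4.57-fold. Other probes gave log2 differences of -0.32 for Wdr82, and of -0.50 and -2.35 for Ncam1. Extracellular matrix genes were lower for 8 of 24 members, with Col1a1 2.94-fold lower, while Col1a2 was 2.52-fold higher. Macrophage markers had a median of -0.39, with Fcgr3 3.20-fold lower.

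After ISD, interferon-stimulated genes were at similar levels in TKO and WT cells, with a median of -0.06 over 55 genes, 5 of them at least 2-fold higher and 0 lower. The higher ones included Ifi211 (at least 22.7-fold), Trim30a (17.4-fold), Ifi205 (8.73-fold) and Ifi204 (6.08-fold). Ifnb1 differed by 1.02-fold, Ccl5 by 1.21-fold and Il6 by 1.32-fold, while Tnf was 2.01-fold higher in TKO cells, where its second probe fell short of 2-fold (log2 difference 0.72). Type I interferon genes were lower for 7 of 11 members, with Ifna14 at 7.74-fold, Ifna5 at 4.62-fold and Ifna11 at 4.02-fold; interferon alpha genes are close in sequence, so their probes may share targets. Il1b was 8.05-fold lower, and cell cycle genes were lower for 10 of 32 members and higher for 2. Macrophage markers had a median of -0.42 and fibroblast markers of -0.41. Fcer1g (at least 548-fold), Csprs (at least 21.6-fold), Ifi213 (12.7-fold) and Ear3 (at least 10.5-fold) were higher, and Ifi202b (at least 123-fold), Serpina3n (at least 20.6-fold), Igfbp2 (10.1-fold), Cdsn (9.52-fold) and Fcrls (9.38-fold) lower. Counts were 217 higher and 367 lower of 9077 genes.

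STKO cells after ISD were below TKO cells after ISD in 51 of 54 interferon-stimulated genes, with a median of -3.36. Cxcl9 was at least 451-fold lower, Oasl1 at least 368-fold, Ifnb1 179-fold, Ifi205 166-fold, Cd69 127-fold and Gbp5 121-fold. Cxcl10 was 42.3-fold, Ccl5 40.0-fold, Il6 14.3-fold, Ifna4 at least 13.8-fold and Tnf 8.30-fold lower. The other Cxcl10 probe gave a log2 difference of -4.44 against -5.40. Antigen presentation genes were lower for 16 of 24 members, with Tap1 at 12.3-fold, and NF-kappaB targets for 12 of 25, with Cd40 at 22-fold. Cell cycle genes were higher for 15 of 33 members (median 1.08, or 0.88 with undetected signals raised), including Cdc20 (4.82-fold), Cenpa (4.76-fold) and Aurka (4.18-fold). Serpina3n (at least 19.0-fold), Hpgd (10.5-fold), Slco4a1 (9.91-fold), Arhgef39 (at least 9.88-fold), Ddit4l (8.41-fold) and Mbp (7.86-fold) had the largest upward differences. In total 531 of 9414 genes were higher and 632 lower. With median scaling in place of quantile normalization the median of all genes moved by -0.11 in this comparison and by 0.10 in the WT response.

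**Figure D4:**
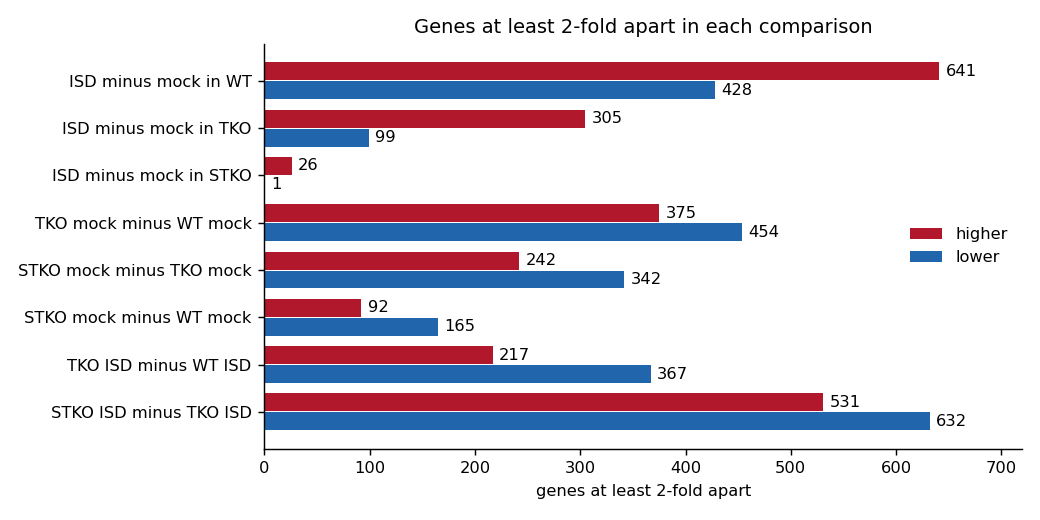
Number of genes (x axis) at least 2-fold higher (red) and lower (blue) in each comparison (y axis). The STKO response to ISD held 26 higher genes and 1 lower gene, against 641 and 428 in WT cells.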

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

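Chac1, a stress-induced enzyme of glutathione breakdown, and Spic, a macrophage transcription factor, went in opposite directions after ISD in WT and STKO cells. Chac1 differed by -1.25 on the log2 scale in WT and by 1.04 in STKO cells, a gap of -2.29. Spic differed by -1.11 in WT and by 1.15 in STKO cells, a gap of -2.25. Each passed 2-fold in both genotypes, and the differences were not tested, since each value rests on a pair of arrays.

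Probes with no listed gene were left out of the comparisons, yet some were brighter after ISD than in mock cells of the same genotype. At least 2-fold higher were 116 of 2150 such probes in WT, 57 of 2111 in TKO and 5 of 2130 in STKO cells.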

How the results depend on the processing

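No comparison of single arrays could be checked by leaving out a replicate. No paired analysis was run, since each comparison sets 1 array against 1. Dim probes limit these results, since a signal near background is compressed when background is kept. Over the alternatives tried, 91 counts stayed within 1.5 times and 69 did not. Of the medians of interferon-stimulated genes and macrophage markers and the levels of Trex1 and Sting1, 128 moved by no more than 0.30 on the log2 scale, the largest pooled SD between probes of a gene, and 24 moved more. All 24 correlations between responses stayed within 0.1. Of the values of single genes named by the fixed rule, 485 moved by more than 0.30 and 995 did not. Without background correction 113 moved and 72 did not, with Ifnb1 in the WT response at 7.96 in place of 9.12. No called gene named by the rule changed sign. Where background was kept, lower counts follow from the construction; for other shifts the cause was not tested.

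Without background correction, the counts of higher genes were 14 in the STKO response, 140 in STKO against TKO mock, 50 in STKO against WT mock, 121 in TKO against WT ISD and 298 in STKO against TKO ISD. The counts of lower genes there were 225 in the WT response, 31 in the TKO response, 0 in the STKO response, 265 in TKO against WT mock, 90 in STKO against WT mock and 204 in TKO against WT ISD. The interferon-stimulated gene median was 2.32 in the WT response, 1.79 in TKO against WT mock, -2.44 in STKO against TKO mock, -2.96 in STKO against TKO ISD, -1.67 in TKO minus WT response and -2.16 in STKO minus WT response. Sting1 differed by -0.79 in STKO against TKO mock and -0.95 in STKO against WT mock. Trex1 differed by -2.14 in STKO against WT mock. With normexp without controls, the counts of higher genes were 14 in the STKO response, 142 in STKO against TKO mock, 52 in STKO against WT mock, 124 in TKO against WT ISD and 306 in STKO against TKO ISD. The counts of lower genes there were 229 in the WT response, 33 in the TKO response, 0 in the STKO response, 270 in TKO against WT mock, 92 in STKO against WT mock and 212 in TKO against WT ISD. The interferon-stimulated gene median was 1.80 in TKO against WT mock, -2.45 in STKO against TKO mock, -2.99 in STKO against TKO ISD and -2.16 in STKO minus WT response. Sting1 differed by -0.82 in STKO against TKO mock and -0.98 in STKO against WT mock. With the deposited log2 table, the counts of higher genes were 16 in the STKO response, 147 in STKO against TKO mock, 53 in STKO against WT mock, 134 in TKO against WT ISD and 327 in STKO against TKO ISD. The counts of lower genes there were 246 in the WT response, 38 in the TKO response, 0 in the STKO response, 282 in TKO against WT mock, 102 in STKO against WT mock and 223 in TKO against WT ISD. The interferon-stimulated gene median was 2.33 in the WT response, 1.79 in TKO against WT mock, -2.44 in STKO against TKO mock, -2.96 in STKO against TKO ISD, -1.66 in TKO minus WT response and -2.16 in STKO minus WT response. Sting1 differed by -0.79 in STKO against TKO mock and -0.95 in STKO against WT mock.

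At 1.5-fold, the counts of higher genes were 1122 in the WT response, 765 in the TKO response, 159 in the STKO response, 897 in TKO against WT mock, 855 in STKO against TKO mock, 392 in STKO against WT mock, 770 in TKO against WT ISD and 1483 in STKO against TKO ISD. The counts of lower genes there were 1332 in the WT response, 637 in the TKO response, 79 in the STKO response, 1172 in TKO against WT mock, 768 in STKO against TKO mock, 603 in STKO against WT mock, 979 in TKO against WT ISD and 1203 in STKO against TKO ISD. At 3-fold, the counts of higher genes were 344 in the WT response, 103 in the TKO response, 6 in the STKO response, 168 in TKO against WT mock, 55 in STKO against TKO mock, 27 in STKO against WT mock, 46 in TKO against WT ISD and 128 in STKO against TKO ISD. The counts of lower genes there were 89 in the WT response, 14 in the TKO response, 0 in the STKO response, 109 in TKO against WT mock, 150 in STKO against TKO mock, 38 in STKO against WT mock, 79 in TKO against WT ISD and 338 in STKO against TKO ISD. Both changes of threshold alter the counts by construction. The order of higher and lower counts was opposite to that at 2-fold in the WT response, STKO against TKO mock and STKO against TKO ISD at 1.5-fold, and in TKO against WT mock at 3-fold.

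With a detection p of 0.05, the STKO response held 2 lower genes. Without a detection filter it held 3, and the interferon-stimulated gene median in STKO against WT mock was -0.44. With the mean of detected probes the STKO response held 0 lower genes, and with measured values in place of bounds 3. Median scaling moved no count by more than 1.5 times.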

Other observations

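Macrophage markers were bright on all 6 arrays of these cultures labelled as fibroblasts. Lyz2, a lysozyme of myeloid cells, had normalized log2 signals of 15.13 to 15.22, Adgre1 of 13.41 to 13.98 and the receptor Csf1r of 12.70 to 13.49, and all 8 measured markers were detected on every array. The fibroblast genes Vim (13.06 to 13.60) and Dcn (10.98 to 11.97) were bright as well, while Pdgfrb (6.48 to 7.98) and Lum (5.52 to 7.08) were dimmer. The median of the macrophage markers lay above that of the fibroblast markers on every array, at 12.84 against 10.22 in WT mock cells. The share of each cell type was not measured. Of 10 fibroblast markers 9 were detected on all 6 arrays. Erythroid markers were detected on no array, and 6 of 7 endothelial and 6 of 8 epithelial markers likewise. Among markers of other types, Col2a1 and Sox9 (chondrocyte), Lpl and Pparg (adipocyte), Acta2 and Tagln (smooth muscle), Nes and Fabp7 (neural) and Tnnt1 (skeletal muscle) were detected on all 6. The adipocyte gene Adipoq reached 7.42 and 7.18 on the STKO arrays, against 5.27 to 5.79 on the other arrays. The Y-linked genes Eif2s3y (10.63 to 10.96) and Kdm5d (6.93 to 7.79) were detected on all 6 arrays and Xist on none.

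The tests below were chosen after the results were seen, except that the one on neighbouring gene families was set out before its own result was known, though after the count of close pairs; in the second pattern the members treated singly were also chosen after their shares were seen.

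A set of 65 genes placed in the RefSeq gene order differed at least 2-fold the same way between WT and both Trex1-deficient genotypes, with and without ISD. Of these, 21 were higher and 44 lower in the deficient cells, led by Fcer1g and Ifi202b. Of 24 members with a second probe, 18 (75%, exact 95% interval 53.3 to 90.2) had all second probes differing at least 1.5-fold the same way. For these 18, a sequence variant under a single probe was argued against as the whole cause. It remains open for Taf6, Wdr82, Ncapg2, Ncam1, Vcan and C1qtnf3, where at least 1 second probe fell short. For the 41 members without a second probe, Fcer1g among them, such variants were not tested. Member pairs at most 10 measured genes apart numbered 13, against a mean of 4.05 in random sets (permutation p = 0.0001, the smallest 10000 sets can give). Of draws from genes called in the WT response, 0.07% held as many. Those draws show how closely ISD-responsive genes lie. They cannot decide whether neighbouring gene families differ between genotypes without ISD. Prl2c3 lies beside Prl2c2, and P2ry13 beside P2ry12, among the members. Blocks of inherited DNA that differ between the embryos are a candidate explanation. For 56 members on other chromosomes, DNA around the targeted Trex1 locus cannot act as a variant in the genes themselves. Whether such DNA alters genes on other chromosomes was not tested. Near Trex1, a window of the 100 nearest measured genes could not tell such DNA apart from chance, with 2 members against a mean of 0.66. Rpl29, Wdr82, Pik3r4 and Lars2 lay just outside, at 52, 57, 58 and 69 genes, so a wider window would hold more members. The first 3 form with Parp3 a run of 4 members within 12 measured genes. A second Wdr82 probe gave log2 differences of only -0.56 in TKO and -0.32 in STKO against WT mock cells. The larger of the 2 runs lay on another chromosome. It held Nuf2, Rgs4, Fcgr3, Fcer1g and Adamts4, 5 members within 18 measured genes. Genotype and culture remain open and untested.

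The 26 genes at least 2-fold higher after ISD in STKO cells are a second pattern. Noise between single arrays was argued against for 19 of them, since these were also at least 2-fold higher in WT cells, where independent lists would share 1.54. For the others, such as Cxcl2 and Malt1, noise remains open, and Chac1 and Spic were lower in WT cells. A small share of STING-competent cells or RNA in the STKO culture was weighed as a cause. If WT and measured on a linear scale, it would bring every induced transcript in 1 proportion of its WT increase. A share of TKO cells or RNA was not modelled. Cxcl10 in WT cells after ISD (signal 43153) lay near the highest signal of that array, 48100, and linearity was not tested. For the 19 members as a set, a test at their median share could not decide on such a mixture. Of the 20 genes with the largest WT increase, 9 are themselves members. At the median share of the members, 8.07%, 7 of the 11 others stayed below the level needed by more than the spread of genes short of 2-fold in WT cells, with Cxcl9 at 0.019%, Ccl5 at -0.29% and Mmp13 at -0.95% of the WT increase. Ccl7 (20.6%), Ccl4 (19.2%), Ccl3 (5.44%) and Irgm1 (5.22%) did not. For Cxcl9, Ccl5, Gbp2 and Ifit2 the level needed, even less that spread, lay over 2-fold above their STKO mock signal. As genes that are not members they were short of 2-fold, so they had to miss it. Among the 9 members only Irf1 reached its level, so the median share does not describe the members either. Members were also taken singly, each with its own share lowered by that spread. Then 15 of them, including Cxcl10 (2.13%), Ifit3 (2.08%) and Rsad2 (2.60%), each left at least 3 of the 20 genes short. That bears only on a share of WT cells or RNA with linear signals. For Ifnb1, Cd69, Cmpk2 and Acod1, with shares of 0.44% to 0.95%, such a mixture cannot be told apart from a response of the STKO cells themselves. For each of these members at most 2 of the 20 genes, Cxcl9 and Ccl5, fell short. Whether any response in STKO cells was independent of STING was not tested.

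The smaller response of interferon-stimulated genes in TKO than in WT cells had a median of -1.98 on the log2 scale. Compression of bright signals was argued against, since 20 members that stayed under a normalized log2 signal of 11 had a median of -1.76 (quartiles -2.30 and -1.16). Over the whole list the median difference from WT was 2.14 in mock cells and -0.060 after ISD (quartiles -0.25 and 0.19), which restates the smaller response and explains nothing. A limit common to both genotypes and the kinetics at 6 h were not tested.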
